A study of Rattus norvegicus with 12 samples.

How the data were processed

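RNA from the hippocampus, frontal cortex and pituitary gland of male Sprague-Dawley rats aged 6 weeks was sequenced in 4 groups. Per the labels, the tissues were frozen on dry ice, RNA was taken up in Trizol and libraries were made with an Illumina TruSeq kit from total RNA. The deposited tables hold read counts per gene and RPKM per gene for 12 libraries, 1 column for each of 3 tissues and 4 groups. The count values were used as deposited and are whole numbers; per the submitters' processing notes Bowtie, edgeR and the build Rnor_5.0 were used, with no version or role given. How reads were counted and the strand setting are not given in the sources used here, so reads of overlapping genes and of close paralogs (class I and II histocompatibility genes, Pcdhg, haemoglobin, Ifit, Mx and Oas genes) may not be told apart. The RPKM values were made by the authors and deposited beside the counts, and the gene length behind them is not the length column of the table. The length implied by counts and RPKM had a median CV of 0.341% and a 99th percentile of 1.33% across libraries, over 10750 genes with RPKM above 5. The count table lists 20859 genes and the one of RPKM has 21090. The 231 genes found only in the RPKM table reach at most 1.24 RPKM. Ensembl gene identifiers name the genes, since 133 symbols are shared by more than 1 gene.

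The tests, settings, named-genes rule and most alternatives were chosen before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The model had additive terms for treatment and tissue over all 12 libraries, a fit planned for the case of 1 library per tissue and group, and left 6 residual degrees of freedom. It tested 14883 genes with a common biological coefficient of variation of 0.120. Contrasts were the 3 pairs of tissues and 4 pairs of treatments: model against control, fluoxetine against model, acupuncture against model and acupuncture against fluoxetine. An effect that differs between tissues enters the error of this model. Gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and again with a correlation estimated per list; adjusted p are over the lists of a comparison. The fry test was run beside camera as planned, and its unadjusted p are not given here. The 31 lists of cell types, pathways and hormones were fixed beforehand. A further 9 were chosen after values were seen: type I interferon stimulated, interferon gamma induced and class II, homeostatic microglia, haemoglobin, brain neuron, intermediate lobe melanotroph, corticotroph receptor (with the transcription factor Tbx19), other anterior hormone and posterior lobe pituicyte. Lists under 5 genes were not tested. Named genes were up to 10 with the largest fold in each direction among those past the threshold, with a mean log2 CPM of at least 1 and a proper symbol, and up to 4 with the lowest p of each list, besides a fixed panel; some genes that this rule picks are not reported here. The genes in the figures were chosen after values were seen. Genes with 0 reads throughout a tissue are given as levels, not as folds.

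Within a tissue, each of the 12 comparisons sets 1 library against 1 other with no test. Log2 ratios of TMM-scaled counts are given for genes with at least 100 reads in both libraries together, with 95% counting intervals. A library at 0 reads enters at a floor of 3 counts. Levels are CPM from edgeR, with TMM-scaled library sizes unless stated. Intervals and floors cover counting error only. The 10 largest ratios in each direction were named. List medians used members with at least 20 reads and are placed among 10000 random lists of the same size drawn from 20 bins of expression. Random members were drawn independently, so these lists lack the correlation between genes of a list, and percentiles may look too extreme. For lists chosen after values were seen, percentiles rest on genes picked with that knowledge. Fold-change correlations used a prior count of 2 and 20 simulations with no change. Overlaps were set against the lowest-p genes of 20 simulated data sets with no change, in lists as long as the observed ones, a comparison chosen after the overlaps were seen. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.

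The fits were tested on simulated data, with 200 changed genes in each of 3 simulations per fold size, a number settled after a first single simulation. For model against control, 33.5% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 82.3% of those changed 3-fold were recovered. The false share of calls was 12.2%, 8.20% and 7.49%, above the nominal 5%. For frontal cortex against hippocampus, 46.5%, 73.2% and 85% were recovered, with false shares of 8.82%, 9.30% and 6.59%.

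Alternatives planned and run were RLE size factors, no low-count filter, DESeq2 1.42.0, the estimated list correlation, correlations over genes with mean log2 CPM of at least 3 and panel levels as RPKM. Chosen after the data were seen were fits on only the compared libraries, leave-one-out fits by tissue or treatment, and RLE, total-read and RPKM scaling of the within-tissue ratios. Planned tests within a tissue (edgeR, DESeq2, limma on RPKM, a fold threshold, a replicate block, leaving out replicates) and tests of tissue by treatment interaction were not run, because each tissue and group had 1 library. A table of RefSeq symbols matched none of the gene identifiers and was not used. No reads were aligned here.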

Results

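RNA was sequenced from the hippocampus, the frontal cortex and the pituitary gland of male Sprague-Dawley rats in 4 groups. The model group was restrained for 6 h a day over 28 days, a procedure used to induce a state like depression. The fluoxetine group received this serotonin reuptake inhibitor by gavage at 10 mg/kg, and the acupuncture group was needled at 2 points on the head (GV20 and GV29), in both cases 1 h before each restraint. The control group is labelled only as control. The deposited tables held 12 libraries, 1 for each tissue and group. The study describes triplicates and 48 rats, and whether a library pooled RNA or reads of several rats is not stated. There were thus no replicates within a tissue and group. Libraries held between 7924535 reads (fluoxetine hippocampus) and 10078788 reads (fluoxetine pituitary). A floor of 3 counts, used for a gene at 0 reads, corresponds to 0.239 TMM-scaled CPM in the fluoxetine pituitary library and 0.403 in the fluoxetine hippocampus library. The mitochondrial gene Mt-co1 had the most reads in all 8 brain libraries. Pomc, the precursor of corticotropin and of melanocyte-stimulating hormone, led in the control, model and acupuncture pituitary libraries with 6.68%, 5.66% and 5.25% of reads. Gh1, growth hormone, led in the fluoxetine pituitary library with 3.47%. Identifiers below are Ensembl genes with the symbols and chromosomes of the tables, which give no coordinates.

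The comparison of frontal cortex with hippocampus, not itself a stated aim, shows how far these tissues differ on average over the 4 groups, restrained ones included. Genes of hippocampal neurons stood lower in the frontal cortex and genes of cortical neurons higher. Mef2c, a transcription factor of cortical neurons, stood higher by 2.52 ± 0.11 (log2 fold change ± SE, 4 libraries per tissue, edgeR adjusted p = 1.7e-09) and Cux2, of upper cortical layers, by 2.29 ± 0.18. Nts, the precursor of neurotensin, differed by -8.23 ± 0.36 (edgeR adjusted p = 1.5e-09), and C1ql2, made by dentate granule cells, by -6.76 ± 0.40. Each of these genes differed in the same direction in 4 of 4 pairs of libraries. In edgeR, 2187 genes were higher and 1895 lower among 14883 tested. Of 13 hippocampal neuron genes, 9 were lower and 4 did not pass, over all genes and adjusted over the list alone. The camera test of this list gave an adjusted p = 5.28e-08, and adjusted p = 0.0586 with an estimated correlation. Of 15 cortical neuron genes, 9 were higher, 2 lower and 4 did not pass, again the same adjusted over the list alone (camera adjusted p = 0.000113, and adjusted p = 0.0586 with an estimated correlation). Choroid plexus genes were lower for 12 of 15 members (13 adjusted over the list alone), among them Ttr, the thyroxine carrier of cerebrospinal fluid, at -7.29 ± 0.73. This list had a camera adjusted p = 1.41e-06, and adjusted p = 0.485 with an estimated correlation. Oligodendrocyte genes were lower for 13 of 17 members (16 adjusted over the list alone), with a camera adjusted p = 9.53e-05, and adjusted p = 0.67 with an estimated correlation. Immediate early genes were higher for 15 of 24 members and lower for 3, the same adjusted over the list alone. Egr1 stood at 1.28 ± 0.18 and Nr4a2 at -2.00 ± 0.28. Their camera adjusted p was 0.00244, and adjusted p = 0.597 with an estimated correlation.

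Hormone genes set the pituitary gland apart from the hippocampus, and genes of neurons and glia stood lower in it. Gh1 was higher by 16.55 ± 0.37 and Prl, prolactin, by 16.20 ± 0.30, with edgeR adjusted p = 6.4e-14 and 1.8e-14. Pomc was higher by 13.45 ± 0.33. Fshb, the beta subunit of follicle-stimulating hormone, averaged 364 CPM in the pituitary and had 0 reads in every hippocampal library. Slc17a7, the vesicular glutamate transporter of cortical neurons, differed by -8.77 ± 0.23 and Neurod6, a neuronal transcription factor, by -12.71 ± 0.20, in 4 of 4 pairs each. The largest of these fitted values rest on libraries with few reads in the lower tissue and depend on the prior count of the fit. In total 5668 genes were higher and 5359 lower. All 19 anterior pituitary hormone genes were higher (19 adjusted over the list alone), and the camera call was kept, with adjusted p = 1.74e-49, and adjusted p = 0.00252 with an estimated correlation. Glutamate genes were lower for 23 of 26 members and GABA genes for 18 of 21, with 1 higher, the same adjusted over each list alone. Their camera adjusted p were 3.14e-08 and 1.65e-07, and adjusted p = 0.289 and adjusted p = 0.26 with an estimated correlation. All 14 astrocyte genes were lower (14 adjusted over the list alone; camera adjusted p = 1.65e-07, and adjusted p = 0.268 with an estimated correlation). Ribosomal protein genes were higher for 57 of 66 members (57 adjusted over the list alone; camera adjusted p = 5.17e-06, and adjusted p = 0.488 with an estimated correlation). A list of 15 brain neuron genes, chosen after values were seen, was lower throughout (15 adjusted over the list alone; camera adjusted p = 7.3e-38, and adjusted p = 0.00103 with an estimated correlation). Genes of the mitochondrial genome were lower for all 11 members (11 adjusted over the list alone; camera adjusted p = 0.000336, and adjusted p = 0.514 with an estimated correlation).

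Against the frontal cortex, the pituitary gland again stood higher in hormone genes, with Gh1 at 15.12 ± 0.34, Prl at 14.94 ± 0.28 and Pomc at 12.87 ± 0.32. Cck, the precursor of cholecystokinin, differed by -9.32 ± 0.28 and Slc17a7 by -8.41 ± 0.23, in 4 of 4 pairs, with edgeR adjusted p = 7e-13 and 2.7e-13. In total 5591 genes were higher and 5350 lower. All 19 anterior pituitary hormone genes were higher (19 adjusted over the list alone; camera adjusted p = 1.7e-50, and adjusted p = 0.00119 with an estimated correlation). Cortical neuron genes were lower for 11 of 15 members and higher for 2 (the same adjusted over the list alone), and this call was also kept (camera adjusted p = 9.87e-06, and adjusted p = 0.0349 with an estimated correlation). Endothelial genes were lower for 11 of 12 members and higher for 1 (the same adjusted over the list alone), among them Cldn5, a tight junction protein of brain vessels, at -4.11 ± 0.15. Their camera adjusted p was 1.71e-05, and adjusted p = 0.14 with an estimated correlation.

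The comparison of model with control asks what repeated restraint changed, here as an effect shared by the 3 tissues. The genes that rose most in the model group include chemokines and other products of inflammation, and those that fell most include antiviral genes that answer type I interferon. Ubd (ENSRNOG00000000768, chromosome 20), a ubiquitin-like protein induced by interferon gamma, rose by 5.88 ± 0.92 (log2 fold change ± SE, 3 tissue pairs, edgeR adjusted p = 0.0078). Cxcl1, which attracts neutrophils, rose by 5.04 ± 0.99, Il1b, interleukin 1 beta, by 3.85 ± 0.63, and S100a9, a protein of neutrophils and monocytes, by 3.75 ± 0.56. Ifit1 (ENSRNOG00000019050, chromosome 1), which binds viral RNA, fell by 2.51 on the log2 scale (SE 0.22, edgeR adjusted p = 0.00027). Usp18, a brake on type I interferon signalling, stood at -1.61 ± 0.18, Mx2, an antiviral GTPase, at -1.34 ± 0.15 and Ddx58, the RNA sensor RIG-I, at -1.14 ± 0.16. All of these held in 3 of 3 tissues. Several of the risen genes had few reads in the control libraries, Cxcl1 0 to 3, so their folds are imprecise.

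In edgeR, 244 genes rose and 222 fell in the model group, and 3030 had an unadjusted p under 0.05. In 20 simulations with no change, a mean of 1.35 genes and at most 5 were called. The noise of each library was drawn independently there. A difference between the groups' rats that runs through the 3 tissues could thus not arise in them. Of 27 inflammation genes, 4 rose and none fell (8 rose adjusted over the list alone), among them Icam1, an adhesion molecule for leukocytes, at 1.47 ± 0.36. The camera test gave an adjusted p = 2.4e-06, and adjusted p = 0.852 with an estimated correlation. Of 18 microglia genes, 4 rose (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 7.12e-05, and adjusted p = 0.852 with an estimated correlation). C1qa, which starts the classical complement pathway, averaged 76.0 ± 6.29 CPM in model tissues and 30.6 ± 1.03 in control tissues (SD, n = 3). Of 30 genes in the list of interferon and antigen presentation, 6 rose and 10 fell (13 and 13 adjusted over the list alone). Its median of 0.05 and mean of 0.03 were above 0 while the test pointed down (camera adjusted p = 0.0853). A pair of further lists was therefore drawn up after these values were seen. Their p-values and percentiles, here and below, rest on genes picked with knowledge of these data. Of 24 type I interferon genes, 21 fell (23 adjusted over the list alone), with a median of -0.98, and the camera call was kept (adjusted p = 2.48e-46, and adjusted p = 0.0139 with an estimated correlation). Of 19 genes induced by interferon gamma or encoding class II molecules, 10 rose (19 adjusted over the list alone), with a median of 1.46 and a camera adjusted p = 2.1e-22, and adjusted p = 0.12 with an estimated correlation. Immediate early genes had a median of -0.26, with 1 of 24 fallen, Egr3 at -0.95 ± 0.24 (3 fell adjusted over the list alone; camera adjusted p = 0.00889, and adjusted p = 0.852 with an estimated correlation). Hspb1, a small heat shock protein, rose by 1.25 ± 0.20, in a list with 2 of 21 risen (3 adjusted over the list alone; camera adjusted p = 0.0402, and adjusted p = 0.852 with an estimated correlation). Glucocorticoid responsive genes gave 2 of 23 risen, the metallothionein Mt2A at 1.54 ± 0.21 and Lcn2, lipocalin 2, at 1.73 ± 0.42 (2 adjusted over the list alone; camera adjusted p = 0.177). None of 16 serotonin genes, 16 neurotrophin genes or 12 stress axis genes passed over all genes (0, 0 and 1 adjusted over the list alone; camera adjusted p = 0.625, 0.996 and 0.996). None of 10 homeostatic microglia genes, a list also chosen later, passed over all genes (1 rose adjusted over the list alone; camera adjusted p = 0.803). Oligodendrocyte genes had a median of 0.36 with none of 17 passing, also adjusted over the list alone (camera adjusted p = 0.00876, and adjusted p = 0.852 with an estimated correlation). In the pituitary gland alone, the oligodendrocyte median against control was 3.0, a value that rests on 1 library per group. Haemoglobin genes, chosen later too, had 2 of 5 fallen (5 adjusted over the list alone), with a median of -0.94 and a camera adjusted p = 4.18e-05, and adjusted p = 0.185 with an estimated correlation. The count depended on the tissues: without the hippocampus 0 genes were called, without the frontal cortex 3, and without the pituitary gland 1130 (577 higher, 553 lower). The balance of directions varied with the setting, with 246 higher and 288 lower under RLE factors, 343 and 420 with DESeq2 and 482 and 369 with no low-count filter. The fit held 1 library per tissue and group, so its p-values measure the spread across tissues, which may come from the same rats, and any other difference between the groups' rats is carried along.

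**Figure D1:**
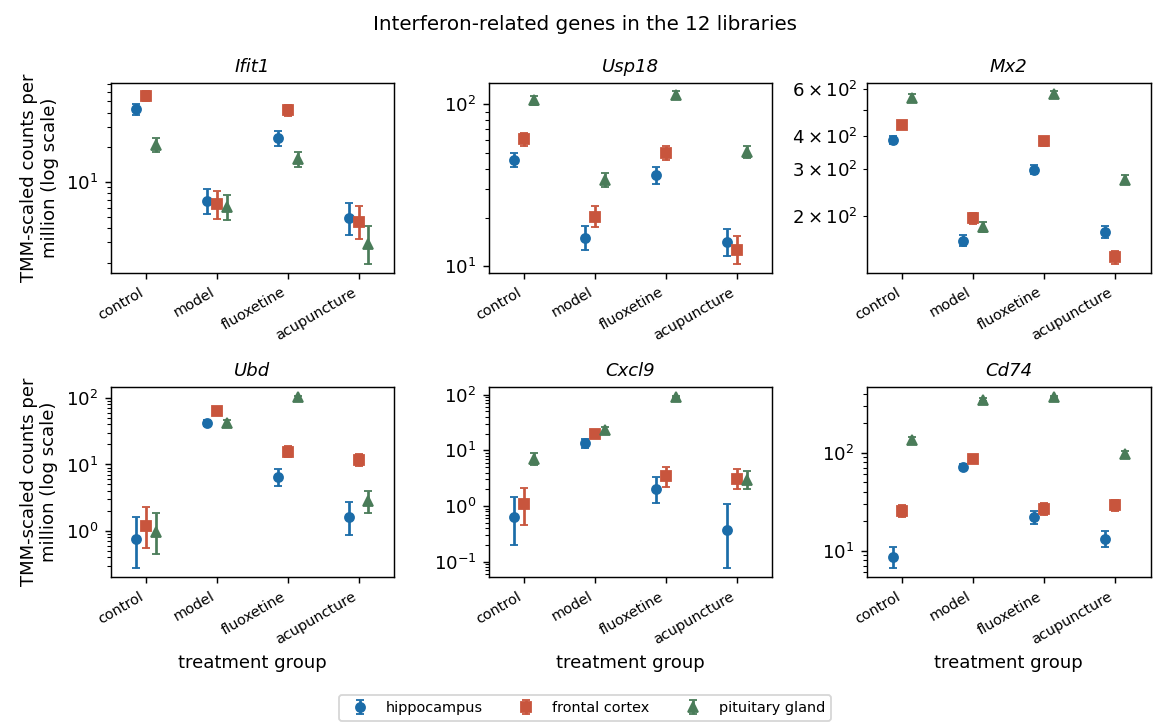
TMM-scaled CPM (log scale) of 6 interferon-related genes by treatment group, with 1 point per library and the 3 tissues told apart by colour and marker; bars are 95% counting intervals. Ifit1, Usp18 and Mx2 stood lower in the model than in the control library of each tissue, and Ubd, Cxcl9 and Cd74 higher.

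The comparison of fluoxetine with model asks what the drug changed in restrained rats. Genes that answer type I interferon were among the few that rose with fluoxetine. Ifit1 rose by 1.97 ± 0.23 (edgeR adjusted p = 0.0063), Usp18 by 1.46 ± 0.18 (0.0071), Mx2 by 1.17 ± 0.15 (0.0097) and Irf7, a transcription factor of the interferon response, by 0.90 ± 0.12 (0.0097), each in 3 of 3 tissues. Ddx60, Oasl2, Ddx58, Rtp4, Eif2ak2 and Irf9 rose as well, by 0.63 to 1.22. The only fallen gene was Chia, an acidic chitinase, at -5.14 ± 0.84 (edgeR adjusted p = 0.037, lower in 2 of 3 tissues), whose reads lay almost wholly in the pituitary libraries. In edgeR 10 genes rose and 1 fell, with 1511 at an unadjusted p under 0.05. Of the 24 type I interferon genes 10 rose (24 adjusted over the list alone), with a median of 0.84, and the call was kept (camera adjusted p = 2.12e-65, and adjusted p = 0.00661 with an estimated correlation). This list was drawn up after the model against control values were seen, and the model libraries are shared. A rise is thus favoured here even without an effect, also in the comparisons within a tissue. The fixed list of interferon and antigen presentation had 5 of 30 risen (13 rose and 3 fell adjusted over the list alone; camera adjusted p = 1e-10, and adjusted p = 0.728 with an estimated correlation). The interferon gamma and class II genes had a median of -0.23 and none passed, also adjusted over the list alone (camera adjusted p = 0.00072, and adjusted p = 0.624 with an estimated correlation). Within a tissue, as given below, their medians were negative in the hippocampus and frontal cortex and positive in the pituitary gland. Ribosomal protein genes had a median of -0.15 and none of 66 passed (5 fell adjusted over the list alone; camera adjusted p = 2.96e-08, and adjusted p = 0.728 with an estimated correlation). Nuclear genes of oxidative phosphorylation had a median of -0.14 and none of 67 passed, also adjusted over the list alone (camera adjusted p = 3.52e-05, and adjusted p = 0.728 with an estimated correlation). Among lists chosen later, none of 7 melanotroph genes passed (3 fell adjusted over the list alone; median -0.43, camera adjusted p = 0.0294, and adjusted p = 0.415 with an estimated correlation). None of 6 other anterior hormone genes passed either (1 fell adjusted over the list alone; median -0.23, camera adjusted p = 0.0376, and adjusted p = 0.356 with an estimated correlation). None of 16 serotonin genes passed, also adjusted over the list alone (camera adjusted p = 0.602; median 0.12, mean -0.08, test pointing up). Without the hippocampus 1 gene was called, without the frontal cortex 2, and without the pituitary gland 367. The balance of risen and fallen genes also varied, with 192 higher and 175 lower without the pituitary gland, 31 and 19 with no low-count filter and 27 and 8 with DESeq2.

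The comparison of acupuncture with model asks what needling changed in restrained rats. The genes that fell most in the acupuncture group include class II histocompatibility genes and products of leukocytes. C3, the central complement protein, fell by 2.70 on the log2 scale (SE 0.31, edgeR adjusted p = 0.0022), and Ubd stood at -3.43 ± 0.70 (0.04). RT1-Da, a class II histocompatibility gene, stood at -2.27 ± 0.32 (0.0067), Gbp2, an interferon-induced GTPase, at -2.31 ± 0.32 (0.0063), and Itgal, a leukocyte integrin, at -2.28 ± 0.35 (0.012). Hapln1, a link protein of the matrix around neurons, rose by 1.04 ± 0.20 (0.03). Each held in 3 of 3 tissues. In edgeR 21 genes rose and 80 fell, with 1981 at an unadjusted p under 0.05. Of the 30 genes in the fixed interferon and antigen list, 15 fell (24 adjusted over the list alone; camera adjusted p = 4.29e-36, and adjusted p = 0.103 with an estimated correlation). Of the 19 interferon gamma and class II genes 12 fell (19 adjusted over the list alone), with a median of -1.99 (camera adjusted p = 5.73e-45, and adjusted p = 0.0514 with an estimated correlation). As this list too was drawn up after the model against control values were seen, the shared model libraries favour a fall. Type I interferon genes had a median of -0.39, with 3 of 24 fallen (13 adjusted over the list alone; camera adjusted p = 2.45e-12, and adjusted p = 0.134 with an estimated correlation). Microglia genes had 4 of 18 fallen (11 fell and 1 rose adjusted over the list alone; camera adjusted p = 2.59e-13, and adjusted p = 0.196 with an estimated correlation), with C1qa at -1.53 ± 0.15 and Aif1, a marker of microglia, at -1.26 ± 0.20. None of 27 inflammation genes passed over all genes (11 fell adjusted over the list alone; median -0.83, camera adjusted p = 2.67e-12, and adjusted p = 0.196 with an estimated correlation). Among glucocorticoid responsive genes, Mt2A fell (-1.19 ± 0.20), 1 of 23 (7 fell adjusted over the list alone; median -0.37, camera adjusted p = 1.13e-07, and adjusted p = 0.103 with an estimated correlation). Lists of other cell types and RNA content were also called in this fit. Choroid plexus genes had a median of -1.17 with none of 15 passing (4 fell adjusted over the list alone; camera adjusted p = 8.01e-06, and adjusted p = 0.597 with an estimated correlation). Oligodendrocyte genes had -0.39 with none of 17 passing, also adjusted over the list alone (camera adjusted p = 0.00142, and adjusted p = 0.796 with an estimated correlation). The mitochondrial genome had 0.26 with 1 of 11 risen (4 adjusted over the list alone; camera adjusted p = 0.000682, and adjusted p = 0.727 with an estimated correlation). Haemoglobin genes had a median of 0.94 with none of 5 passing over all genes (3 rose adjusted over the list alone; camera adjusted p = 3.52e-05, and adjusted p = 0.176 with an estimated correlation). Of the choroid plexus genes, Ttr stood at 1542 CPM in the model and 110 in the acupuncture hippocampus, beside 39.7 and 1.91 in the frontal cortex. How much choroid plexus each dissection held was not tested. In the pituitary gland, the oligodendrocyte list had log2 medians against control of 3.0 (model) and 1.44 (acupuncture). Neither list median need thus be shared by the 3 tissues. Without the hippocampus 2 genes were called, without the frontal cortex 0, and without the pituitary gland 782. The balance of directions depended on the setting, with 408 higher and 374 lower without the pituitary gland, 93 and 169 with DESeq2 and 94 and 248 with no low-count filter.

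Set against each other, the treated groups differed in antiviral genes that answer type I interferon, several of which were among the genes most strongly lower with acupuncture. Ifit1 was lower with acupuncture than with fluoxetine by -2.67 ± 0.24 (edgeR adjusted p = 0.00017), Irf7 by -1.58 ± 0.13 (6.7e-05), and Mx1, an antiviral GTPase, by -1.94 ± 0.23 (0.0008). C3 stood at -2.01 ± 0.32 (0.0065) and C1qa at -1.22 ± 0.15 (0.001), all in 3 of 3 tissues. In edgeR 6 genes were higher and 81 lower, with 1207 at an unadjusted p under 0.05. Of the 30 genes in the fixed interferon and antigen list 21 were lower (27 adjusted over the list alone), with a median of -1.30. This was the only fixed list whose call in a treatment comparison was kept (camera adjusted p = 1.27e-101, and adjusted p = 0.0203 with an estimated correlation). Of the type I genes 23 of 24 were lower (24 adjusted over the list alone; camera adjusted p = 1.26e-140, and adjusted p = 0.000704 with an estimated correlation). Of the interferon gamma and class II genes 8 of 19 were lower (16 adjusted over the list alone; camera adjusted p = 3.89e-35, and adjusted p = 0.0325 with an estimated correlation). Oligodendrocyte and choroid plexus genes had medians of -0.49 and -1.08 with none passing (0 and 3 lower adjusted over the list alone; camera adjusted p = 3.12e-05 and 0.00012, and adjusted p = 0.584 and adjusted p = 0.543 with an estimated correlation). Ttr stood at 110 CPM in the acupuncture and 1428 in the fluoxetine hippocampus, but at 1.91 and 0 in the frontal cortex. In the pituitary gland, the oligodendrocyte list had log2 medians against control of 1.44 (acupuncture) and 4.22 (fluoxetine). Neither list median need thus be shared by the 3 tissues. Chia was called 32.1-fold higher (0.011) but in only 1 of 3 tissues, and DESeq2 gave -0.80 for it (adjusted p = 0.999). Oacyl, an acyltransferase gene, was called higher at 2.91 ± 0.56 (0.028) in 2 of 3 tissues. It had 1112 reads against 139 in the pituitary gland, but 5 against 5 in the hippocampus and 18 against 12 in the frontal cortex. Its call thus rests largely on the pituitary pair, and it is taken up below as a melanotroph marker. Without the hippocampus 26 genes were called, without the frontal cortex 11, and without the pituitary gland 90 (14 higher, 76 lower).

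Further lists were called by camera in these 4 comparisons, most with few members or none passing over all genes. Between model and control, endothelial genes had 1 of 12 risen (4 adjusted over the list alone), with a median of 0.25, and ribosomal protein genes 2 of 66 (5 adjusted over the list alone), with a median of 0.11. The camera adjusted p = 0.0101 and 0.013, and adjusted p = 0.852 with an estimated correlation for both. The mitochondrial genome had a median of -0.26 with 1 of 11 risen (1 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.025, and adjusted p = 0.852 with an estimated correlation). Between fluoxetine and model, astrocyte genes had a median of 0.20 and heat shock genes of -0.09 with none of 14 and none of 21 passing (0 and 2 fell adjusted over the list alone; camera adjusted p = 0.0102 and 0.00232, and adjusted p = 0.866 and adjusted p = 0.728 with an estimated correlation). Between acupuncture and model, 1 of 21 heat shock genes fell (2 adjusted over the list alone; camera adjusted p = 0.00108, and adjusted p = 0.542 with an estimated correlation). Endothelial and neuropeptide genes had medians of -0.14 and 0.31 with none passing, also adjusted over the list alone (camera adjusted p = 0.0233 for both, and adjusted p = 0.50 and adjusted p = 0.727 with an estimated correlation). Of 15 brain neuron genes, a list chosen later, 1 rose (3 adjusted over the list alone; camera adjusted p = 0.000482, and adjusted p = 0.235 with an estimated correlation).

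Between acupuncture and fluoxetine, the lists of blood and of RNA content were called higher. Haemoglobin genes, chosen later, had a median of 0.96 with none of 5 passing over all genes (4 higher adjusted over the list alone; camera adjusted p = 1.72e-07, and adjusted p = 0.0619 with an estimated correlation). The fixed blood list had a median of 0.61 with none of 8 passing (2 higher adjusted over the list alone; camera adjusted p = 0.00196, and adjusted p = 0.481 with an estimated correlation). The mitochondrial genome had a median of 0.33 with none of 11 passing (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000254, and adjusted p = 0.561 with an estimated correlation). Ribosomal protein genes had 1 of 66 higher and 1 lower, also adjusted over the list alone, and oxidative phosphorylation genes none of 67 (camera adjusted p = 0.00103 and 3.14e-05, and adjusted p = 0.628 and adjusted p = 0.54 with an estimated correlation). Inflammation genes had a median of -0.66 with none of 27 passing (6 lower adjusted over the list alone; camera adjusted p = 2.52e-10, and adjusted p = 0.275 with an estimated correlation). Microglia genes had 2 of 18 lower (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 2.72e-11, and adjusted p = 0.275 with an estimated correlation). Glucocorticoid responsive genes had a median of -0.34 with none of 23 passing (2 lower adjusted over the list alone; camera adjusted p = 8.67e-07, and adjusted p = 0.134 with an estimated correlation). Of lists chosen later, brain neuron genes had a median of 0.16 with none of 15 passing, also adjusted over the list alone (camera adjusted p = 0.00182, and adjusted p = 0.281 with an estimated correlation). Other anterior hormone genes had a median of 0.47 with none of 6 passing over all genes (3 higher adjusted over the list alone), and their call was kept (camera adjusted p = 0.000413, and adjusted p = 0.0325 with an estimated correlation).

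Some genes changed in the model group changed in the opposite direction with treatment, as comparisons that share the model libraries do even without an effect. Of the 244 risen genes, 43 were among the 80 that fell with acupuncture. Independent lists would share 1.31, and in 20 simulations with no change and the same shared libraries, the top genes in lists of the same lengths shared a mean of 20.6 and at most 27. Of the 222 fallen genes, 15 were among the 21 that rose with acupuncture (0.313 for independent lists; simulated mean 9.45, at most 14). All 10 genes that rose with fluoxetine were among the 222 (0.149 for independent lists; simulated mean 5.35, at most 8). The single gene that fell with fluoxetine was not among the 244. Part of each overlap may thus come from the shared libraries, and the excess over these values is not a measure of a shared effect.

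Across 14883 genes, which are not independent replicates, the model and treatment fold changes of the same tissue were set against simulations with the same shared library and no change. In the frontal cortex, r between model and fluoxetine changes was -0.596 (simulated -0.484; covariance -0.185 beside -0.103) and between model and acupuncture changes -0.627 (simulated -0.487; covariance -0.204 beside -0.102). The fluoxetine and acupuncture changes there had r = 0.602 (simulated 0.491; covariance 0.172 beside 0.102). In the hippocampus the 3 values were -0.519 (simulated -0.469; covariance -0.131 beside -0.0964), -0.546 (simulated -0.471; covariance -0.154 beside -0.0958) and 0.521 (simulated 0.471; covariance 0.129 beside 0.0964). In the pituitary gland they were -0.164 (simulated -0.493; covariance -0.0446 beside -0.0933), -0.455 (simulated -0.484; covariance -0.142 beside -0.0939) and 0.327 (simulated 0.506; covariance 0.0824 beside 0.0945). The simulations carry the shared library. In the brain tissues the covariances lay further from 0 than simulated. Over genes with mean log2 CPM of at least 3, this excess was nearly gone in the hippocampus for the pairs of model with fluoxetine changes (covariance -0.0425 beside -0.0389) and of fluoxetine with acupuncture changes (0.0402 beside 0.0380). In the pituitary gland this held only between model and acupuncture changes, where r itself was closer to 0 than simulated; the other pituitary values were closer to 0 in both measures.

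Within the hippocampus each comparison rests on 2 libraries, without a test, and intervals cover counting error only. Between model and control, 97 genes were at least 2-fold higher and 36 at least 2-fold lower among 10778 with 100 reads. Ubd had 400 reads against 6, a log2 ratio of 5.80 (95% counting interval 4.66 to 7.25), and Cd74, the class II invariant chain, 688 against 68, a ratio of 3.08 (2.71 to 3.46). Ifit1 had 65 reads against 339, a ratio of -2.65 (-3.05 to -2.26). The interferon gamma and class II genes had a median of 1.85, at percentile 100 of 10000 random lists matched on expression, and the type I genes -0.83, at percentile 0. Haemoglobin genes had a median of -1.33 (percentile 0) and the mitochondrial genome -0.50 (percentile 0). Between fluoxetine and model, type I genes stood at 0.54 (percentile 100), interferon gamma and class II genes at -1.15 (percentile 0) and glucocorticoid responsive genes at -0.30 (percentile 0), with 15 genes 2-fold higher and 52 lower. Between acupuncture and model, choroid plexus genes stood at -3.05 (percentile 0), with 14 of 14 members at least 2-fold lower. Ttr had 885 reads against 14751, a ratio of -3.81 (-3.90 to -3.71), and Sostdc1, a secreted inhibitor of bone morphogenetic proteins, 12 against 152, a ratio of -3.41 (-4.39 to -2.56). The interferon gamma and class II genes stood at -2.12 (percentile 0), and 19 genes were 2-fold higher and 124 lower. Between acupuncture and fluoxetine, type I genes stood at -1.09 and choroid plexus genes at -2.69 (both percentile 0), with 12 genes 2-fold higher and 53 lower.

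Within the frontal cortex, 147 genes were at least 2-fold higher and 63 lower in the model than in the control library. Serpina3n, a protease inhibitor of reactive astrocytes, had 185 reads against 0, a log2 ratio of at least 5.75 against the floor of 3 counts per library. Ttr had 341 reads against 8, a ratio of 5.22 (95% counting interval 4.22 to 6.44), and C3 had 911 against 113, a ratio of 2.81 (2.53 to 3.11). Ifit1 had 55 against 414, a ratio of -3.11 (-3.54 to -2.70). The interferon gamma and class II genes had a median of 1.54 (percentile 100), inflammation genes 0.72 (percentile 99.99), microglia genes 0.54 (percentile 100) and type I genes -0.79 (percentile 0). Meninges genes stood at -0.60 (percentile 0) and immediate early genes at -0.28 (percentile 0.04). Between fluoxetine and model, 46 genes were 2-fold higher and 77 lower, with type I genes at 0.72 (percentile 100) and interferon gamma and class II genes at -0.80 (percentile 0). Ttr had 0 reads against 341, a log2 ratio of -6.66 or lower against the floor. Between acupuncture and model, 58 genes were 2-fold higher and 140 lower. Serpina3n had 8 reads against 185, a ratio of -4.50 (-5.73 to -3.49), the interferon gamma and class II genes stood at -1.62 (percentile 0), and haemoglobin genes at 1.23 (percentile 100). Between acupuncture and fluoxetine, 17 genes were 2-fold higher and 60 lower, with type I genes at -1.54 (percentile 0).

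Within the pituitary gland, myelin and astrocyte transcripts stood far higher in the model than in the control library. Mobp (ENSRNOG00000018700), a myelin protein gene, had 6476 reads against 27, a log2 ratio of 7.63 (95% counting interval 7.09 to 8.24). Mag, another myelin gene, had 244 against 1, a ratio of 7.66 (5.17 to 12.97), and Gfap, an astrocyte filament protein, 2695 against 73, a ratio of 4.94 (4.60 to 5.29). The oligodendrocyte list had a median of 3.0 (percentile 100), with 15 of 17 members at least 2-fold higher, and the astrocyte list 0.84 (percentile 100). Inflammation genes stood at 0.85 and interferon gamma and class II genes at 1.23 (both percentile 100), type I genes at -1.17 and immediate early genes at -0.41 (both percentile 0). In total 184 genes were 2-fold higher and 72 lower. Between fluoxetine and model, Pomc had 165906 reads against 536342, a ratio of -1.87 (-1.88 to -1.86). Oacyl had 139 against 1322, a ratio of -3.43 (-3.69 to -3.17), and Pax7, a transcription factor of intermediate lobe cells, 49 against 238, a ratio of -2.46 (-2.93 to -2.01). The intermediate lobe list had a median of -0.51 (percentile 0.02). Pmch (ENSRNOG00000004632), the precursor of melanin-concentrating hormone, had 255 reads against 4, a ratio of 5.82 (4.44 to 7.70). Type I genes stood at 1.24 and interferon gamma and class II genes at 0.71 (both percentile 100), and 141 genes were 2-fold higher and 48 lower. Between acupuncture and model, Pmch had 280 reads against 4, a ratio of 6.23 (4.85 to 8.11), and Gad1, which makes GABA, 307 against 44, a ratio of 2.90 (2.44 to 3.39). C3 had 205 against 1505, a ratio of -2.78 (-3.00 to -2.57). Oligodendrocyte genes stood at -1.77, microglia genes at -1.31 and interferon gamma and class II genes at -1.89 (all percentile 0), with 82 genes 2-fold higher and 180 lower. Between acupuncture and fluoxetine, 86 genes were 2-fold higher and 338 lower, and Chia had 284 reads against 6, a ratio of 5.84 (4.70 to 7.30). In that last comparison, scaling by total reads in place of TMM moved the median of all genes from 0.044 to -0.118. It moved it from -0.018 to 0.083 between model and control in the hippocampus.

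**Figure D2:**
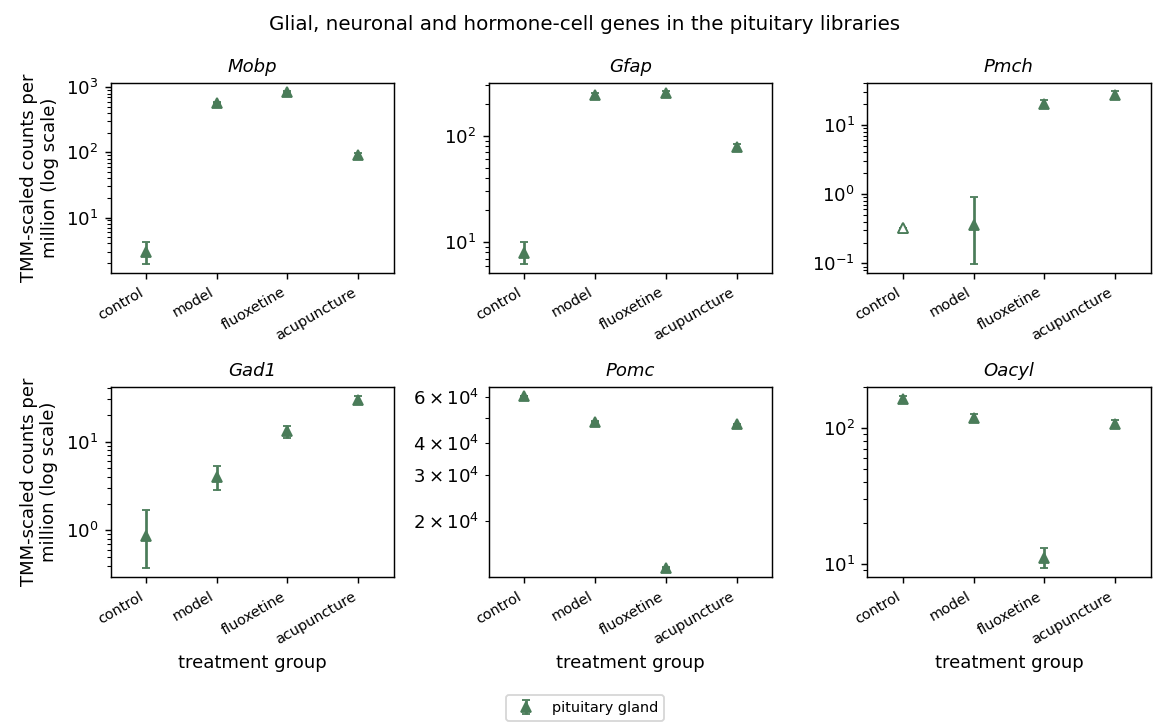
TMM-scaled CPM (log scale) of 6 genes in the 4 pituitary libraries by treatment group, with 1 point per library; bars are 95% counting intervals and a hollow marker is a library with 0 reads drawn at the floor of 3 reads. Mobp and Gfap stood lowest in the control library, Pmch stood at 20.3 and 27.0 in the fluoxetine and acupuncture libraries, and Pomc and Oacyl stood lowest in the fluoxetine library.

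Genes of the stress hormone axis and of neuronal activity, fixed as a panel, differed most between the pituitary libraries. Pomc stood at 60760.5, 48357 and 47142 TMM-scaled CPM in the control, model and acupuncture pituitary and at 13219 in the fluoxetine pituitary. In the order control, model, fluoxetine and acupuncture, Fkbp5, a glucocorticoid-induced chaperone of the glucocorticoid receptor, stood at 244, 214, 217 and 138 in the pituitary, and Fos, an immediate early gene, at 181, 136, 98.7 and 201. Bdnf, a neurotrophin, stood at 24.9, 15.8, 5.50 and 18.7 in the pituitary, 65.0, 52.9, 56.2 and 53.0 in the hippocampus and 62.5, 42.7, 55.2 and 61.7 in the frontal cortex. Crh, corticotropin-releasing hormone, had 0 reads in 3 pituitary libraries and 1.54 CPM in the acupuncture one, and stood at 13.9, 13, 13.5 and 12.7 in the frontal cortex. Slc6a4, the serotonin transporter that fluoxetine blocks, did not exceed 0.653 in any library.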

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

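The lists below moved to opposite sides in a pair of tissues under the same treatment, and none of these differences was tested, since each tissue and group had 1 library. Such pairs were sought among 31 lists and 3 comparisons, as list medians below percentile 0.5 of random lists in one tissue and above percentile 99.5 in the other. This bound was set after a stricter version, with percentiles 0.1 and 99.9 and a median of at least 0.3, had returned 2 of the 8 pairs. Between fluoxetine and model, glucocorticoid responsive genes stood at 0.24 in the pituitary gland and -0.30 in the hippocampus, a difference of 0.537. Glutamate genes stood at 0.30 in the pituitary gland and -0.25 in the frontal cortex, 0.547 apart. Inflammation genes stood at 0.34 in the pituitary gland, 0.717 above the hippocampus and 0.719 above the frontal cortex (-0.38 in both). Oligodendrocyte genes stood at 0.53 in the pituitary gland and -0.32 in the frontal cortex, 0.858 apart. Between acupuncture and model, glutamate genes stood at 0.36 in the pituitary gland and -0.14 in the frontal cortex, 0.492 apart. Immediate early genes stood at 0.56 in the pituitary gland and -0.38 in the hippocampus, 0.945 apart. Meninges genes stood at 0.37 in the frontal cortex and -0.36 in the pituitary gland, 0.726 apart.

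Myelin and astrocyte genes stood higher in 3 pituitary libraries than in the control one, with oligodendrocyte medians of 3.0 (model), 4.22 (fluoxetine) and 1.44 (acupuncture), and Mobp at 584, 848 and 91.8 CPM against 2.94. For this pattern, the tests of brain tissue in all 3 libraries and of the posterior lobe were written before their values were seen. Those of the model and fluoxetine libraries alone and of normalization, whose first bound was replaced, were written after. The brain neuron list used in the tests of brain tissue was itself chosen after other values of these data were seen. If tissue like the cortex or hippocampus libraries had entered the dissection, neuron genes would have reached the same share of brain level as oligodendrocyte genes; their ratio was 0.0144 in the model and 0.0208 in the fluoxetine library, which argues against it there, but 0.413 in the acupuncture library, which leaves it open over all 3. A larger share of posterior lobe would raise the pituicyte markers, whose highest median was -0.0769. Of these 6 genes, a list chosen after values were seen, 3 were higher and 3 lower in the pituitary gland than in the hippocampus. Their median is thus a weak measure of the posterior lobe share and does not settle it. A scaling effect is argued against by list medians that kept at least 0.988 of their size under other scalings. Attached white matter or hypothalamic tissue, which hold few cortical neurons, might give such a pattern and was not tested, and neither was a difference between the rats.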

How the results depend on the processing

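Under RLE factors all 28 counts and correlations, 33 list calls and 107 treatment genes kept their side of the threshold while 3 of 388 tissue genes lost their call, and tissue counts stayed within 1.5 times under every setting. With no low-count filter 851 genes were called between model and control, 50 between fluoxetine and model, 342 between acupuncture and model and 198 between acupuncture and fluoxetine; the cause was not tested. DESeq2 called 763, 35 and 262 in the first 3 comparisons, with the cause not tested; 3 of 107 treatment genes and 6 of 388 tissue genes lost their call, and 1 treatment gene reversed, Chia between acupuncture and fluoxetine, at -0.80 (adjusted p = 0.999), where reads were nearly confined to 1 tissue. The settings that follow were chosen after the data were seen, except where planned is stated. With only the compared libraries in the fit 738 genes were called between model and control. Leave-one-out fits hold fewer libraries. Without the hippocampus and without the pituitary gland, 0 and 1130 genes were called between model and control and 1 and 367 between fluoxetine and model. Without the frontal cortex and without the pituitary gland, 0 and 782 were called between acupuncture and model and 11 and 90 between acupuncture and fluoxetine. Of 388 tissue genes 14 to 24 lost their call without 1 group and 5 with no filter. Of 107 named treatment genes 96 lost their call without the hippocampus and 100 without the frontal cortex, against 8 of 105 without the pituitary gland. As planned, an estimated correlation was used in camera and cost 32 of 33 treatment calls of fixed lists their significance. Over genes with mean log2 CPM of at least 3 (planned; genes are not independent), fewer genes enter and the correlations moved. In the hippocampus they were -0.569, -0.592 and 0.566 (simulated -0.492, -0.489 and 0.484) for model against fluoxetine, model against acupuncture and fluoxetine against acupuncture changes, with covariances of -0.0425, -0.0512 and 0.0402 (simulated -0.0389, -0.0384 and 0.0380). In the frontal cortex they were -0.710, -0.716 and 0.704 (simulated -0.496, -0.495 and 0.50), and in the pituitary gland -0.134 and 0.154 for the first and last (simulated -0.497 and 0.50). Total-read scaling moved 12 of 240 within-tissue ratios beyond their counting interval, and RPKM moved 16 of 89 panel levels. Depth limits genes with few reads, since 3 counts correspond to 0.239 to 0.403 CPM.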

Other observations

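Pmch, Gad1 and Nts differed between the pituitary libraries. Pmch stood at 0, 0.36, 20.3 and 27 CPM in the control, model, fluoxetine and acupuncture pituitary, and Gad1 at 0.87, 3.97, 13.1 and 29.6. Nts stood at 5.11, 1.89, 7.57 and 8.39 in that order. Gad1 is also abundant in the brain libraries, at 148 CPM or more in each, and Nts in the hippocampus, at 77.4 or more. Slc17a7, a transporter of cortical neurons, stood at 1.74, 1.17, 1.27 and 4.43 in the pituitary libraries in the same order. Of these libraries only the acupuncture one had Crh reads, at 1.54 CPM. Whether attached hypothalamic or other brain tissue carried in these transcripts was not tested, so their levels need not reflect pituitary cells. Among hormone genes, Oxt stood at 3.92, 2.79, 6.06 and 5.40, and Avp at 3.05, 4.60, 15.6 and 2.80, lowest with acupuncture where Pmch was highest. The neuropeptide list had a median of 0.92 between fluoxetine and model and 0.83 between acupuncture and model there, both at percentile 100. In the hippocampus, Ttr stood at 2089, 1542 and 1428 in the control, model and fluoxetine libraries and at 110 in the acupuncture library. In the frontal cortex, Ttr stood at 1.07, 39.7, 0 and 1.91 in the 4 groups in that order. Haemoglobin reads stood at 97.8, 47.6, 37.5 and 83.1 CPM, unscaled by TMM, in the hippocampus and at 155, 72.3, 49.1 and 141 in the frontal cortex in the same order. These values have no replicate.

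For the interferon pattern, the test of microglia was written before its value was seen and the tests of blood and normalization after; a first version for blood, lower in all 3 tissues, was not met in the pituitary (median 0.02) and was replaced. In the model libraries interferon gamma and class II genes stood higher and type I interferon genes lower in all 3 tissues. More blood left in the brain, as a source of the interferon gamma rise, would raise haemoglobin genes, whose higher median there was -1.21. In the pituitary their upper quartile was 0.0698, while the lower quartile of the interferon gamma set was 0.74. Haemoglobin genes measure red cells, so this test does not reach leukocytes in the tissue. In the fit over 3 tissues the fixed blood list was split, with 2 of 8 genes risen and 2 fallen (2 and 5 adjusted over the list alone). Its median was -0.82 and its mean 0.23. More microglia would raise homeostatic markers, whose higher median in the brain tissues was -0.30 (0.22 in the pituitary, outside this test). The homeostatic list was chosen after values were seen, and 7 of its 10 genes also sit in another list. In the fit over 3 tissues the fixed microglia list went the other way, with a median of 0.57 and 4 of 18 genes risen. More microglia thus remains open. The type I median stayed at or below -0.71 and the interferon gamma median at or above 1.23 under every scaling. That blood test does not reach the type I fall, so less blood in the brain was tested on its own. It would move type I and haemoglobin genes together in the treated libraries, but against the model library their medians had opposite signs in all 4 comparisons, with a smallest gap of 0.411 between their interquartile ranges. With fluoxetine the medians of type I and haemoglobin genes were 0.54 and -0.19 in the hippocampus and 0.72 and -0.52 in the frontal cortex. With acupuncture they were -0.48 and 0.98, and -0.64 and 1.23. These values argue against blood as the source of the type I differences between treated and model libraries. They do not reach the type I fall from control to model in the brain, where both lists fell. There the type I and haemoglobin medians were -0.83 and -1.33 in the hippocampus and -0.79 and -1.21 in the frontal cortex. Less blood thus remains open for that fall. In the pituitary, haemoglobin stood at 0.02 while the type I median was -1.17. An effect of restraint is a hypothesis left by these tests, as are more microglia and more leukocytes. For the type I fall in the brain, less blood is another. An infection or another difference between the groups' rats might give the same pattern and could not be tested.

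For the fall of Pomc reads in the fluoxetine pituitary library against the model library, both tests were written after the result was seen. A smaller share of intermediate lobe tissue would lower melanotroph markers, whose median was -0.96 with quartiles of -1.75 and -0.21, led by Oacyl at -3.43 and Pax7 at -2.46. Of these 7 genes 6 had at least 20 reads in the model library, and Gabra3 (0.47) and Megf11 (0.08) did not follow. The list set against them gave no clear comparison (median -0.01), with Crhr1 at 0.35 and the glucocorticoid receptor gene Nr3c1 at 0.12 and -0.76 under its 2 identifiers. Its member Tbx19, a transcription factor of melanotrophs as well as corticotrophs, stood at -0.14 and did not follow the melanotroph markers either. A shift of counts to other hormone genes is argued against by their median of -0.13. The value of Pomc is thus consistent with a dissection holding less intermediate lobe (-0.96), so it may say little about regulation by the drug.

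All tests against other splits of the libraries were written after the results were seen. For the 3 tissue comparisons, 1 of 35 splits, the real one, called as many genes (4082, 11027 and 10941), and the highest other split called 4, 0 and 0. Every other split mixed both tissues within a group, which put the tissue difference into the error and left few calls to be made. The splits also ignored the pairing of libraries by treatment group, so no conclusion about chance is drawn from them. For the 4 treatment comparisons, 1 of 10 splits called as many genes (466, 11, 101 and 87), the highest other split called 0, 2, 1 and 1, and with 10 splits the share cannot fall under 0.1.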
